A study of Mus musculus with 2 samples.

How the data were processed

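RNA was measured in cardiac neural crest cells of mouse embryos at embryonic day 14.5. The cells carried a tdTomato reporter switched on by Wnt1-Cre, a driver active in the neural crest, so that descendants of the neural crest in the heart fluoresced red. Hearts were digested with collagenase, tdTomato-positive cells were collected by fluorescence-activated sorting, and total RNA was extracted with a column kit for small samples, per the labels' protocols. The RNA was biotin-labelled and hybridised to the Affymetrix Mouse Gene 1.0 ST array, which carries probes along the whole transcript. The series held 2 arrays, 1 of Adam19+/+ cells and 1 of Adam19-/- cells. The number of embryos behind each sample and their sex are not given in the sources used here.

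The values analysed were log2 signals per transcript cluster, deposited by the authors in a single table of 28853 clusters with 1 column per array. How the authors corrected the background, normalised the arrays or combined probes is not given in the sources used here. The log base is not written in the table either. Read as natural logarithms, the highest value would stand for a linear signal of 2.02e+06, above the 65535 that a 16-bit scanner can record, whereas read as log2 it stands for 23484, so the values were taken as log2. Both columns had the same lowest value, 4.09, held by 44 clusters in the Adam19+/+ column and 41 in the Adam19-/- column, and 15.5% of all clusters had exactly equal values in both. Among the genes above the expression floor described below, 108 had exactly equal values. The values were not normalised again for the main results.

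Clusters were named through the platform annotation of 2016 and, by Entrez identifier, the symbols of a RefSeq gene table of the GRCm38.p6 assembly. Of the clusters, 21789 had 1 gene symbol, 1621 had several and 5443 had no gene listed in the annotation used here. Clusters with several symbols or none were left out of the gene-level results. Among the clusters with 1 symbol, 21698 matched the gene table and 91 kept the older symbol. For a gene with several clusters, the brightest stood for the gene, which gave 19938 genes. An expression floor was set at the median of the genes' mean signal, 8.01 on the log2 scale, and 10122 genes with at least 1 array above it were kept. The floor is a middle level of all genes and not a limit of detection, and a gene may pass it on 1 array only. The gene table was otherwise used for the chromosome of each gene, the order of genes around Adam19 and the window of 20 Mb, and no coordinate is given, since the genome build behind the array's values is not given in the sources used here.

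With 1 array per genotype there is no replicate, so no p-value, standard error or test across samples was computed, and a difference is that of these 2 samples. Differences are log2 signal of Adam19-/- minus Adam19+/+. A gene was counted when this difference reached 2-fold. The gene lists, 26 in all, the thresholds, the rule for named genes and the alternatives were fixed before the data were examined, except 2 alternatives that leave out genes near Adam19. For each list with at least 5 members above the floor, the median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins (Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9). These percentiles describe where a list lies on these 2 arrays. They treat genes as independent, which members of a pathway are not, and they do not measure variation between embryos.

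The rule for named genes took Adam19, the 12 largest increases and the 12 largest decreases above the floor, and up to 4 members of each list with the largest absolute difference, or all members for the list of Xist and Y-linked genes. Symbols of microRNAs, small nucleolar RNAs, predicted genes, Riken clones, and olfactory or vomeronasal receptors stayed in the counts but were not named. Other genes that are named were chosen after their values were seen. Some list members are not analysed here.

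The steps were tested on simulated data made by shuffling the differences of the 10122 genes within bins of signal for this comparison. Of 200 simulated lists of 16 genes with no shift, 2.5% lay above and 3.5% below the central 95% of random lists, and with a shift of 0.1 and 0.2 on the log2 scale 87.5% and 100% lay above it. The lists with no shift were themselves random lists, so their shares check only that the steps ran as intended. Of 50 genes given a 2-fold increase, 64% were counted at the 2-fold threshold. The share was 100% of 50 given a 3-fold increase and 0% of 50 given a 1.5-fold increase. Each increase was added to a shuffled difference, so the 64% is the share of those differences that were not negative. Decreases were not simulated, so these shares do not apply to genes that were lower. The number of arrays limits the precision. Alternatives covered the floor, quantile normalisation, centring on a lowess curve, adding 32 to the linear signal, averaging the clusters of a gene, unnamed clusters, thresholds of 1.5-fold and 3-fold, the mean in place of the median, unmatched random lists, leaving out genes shared between lists, and leaving out genes within 20 Mb of Adam19, for the counts together with those of the Y chromosome.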

Results

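Gene expression was compared between sorted cardiac neural crest cells of Adam19-/- and Adam19+/+ mouse embryos at stage E14.5, to ask which transcripts differ in these cells when Adam19 is missing. Adam19 encodes a membrane-anchored metalloprotease. The cells were tdTomato-positive descendants of the neural crest from the heart, which at this stage include smooth muscle of the great arteries, mesenchyme of the outflow valves, autonomic neurons and glia. There was 1 array per genotype (n = 1), so every difference below is that between 2 samples, without a replicate check. The median log2 signal was 7.49 on the Adam19+/+ array and 7.52 on the Adam19-/- array, and across clusters the arrays correlated with Pearson's r = 0.998. Precision is limited by the number of arrays. Within the arrays, 583 genes had at least 2 clusters above the expression floor, and the differences given by 2 clusters of a gene lay a median of 0.06 apart on the log2 scale, with a 95th percentile of 0.24. For Pgk1, 2 clusters had the same Adam19+/+ value, 11.87, so clusters of a gene are not always independent. This gap holds no variation between samples. Among the 10122 genes above the floor, the central 95% of differences ran from -0.20 to 0.30, with a median of 0.04. More genes were therefore higher than lower. By increase, a gene at 0.02 (Pmel) ranked 5655th and a gene at -0.01 (Mef2c) ranked 6924th. Counts of higher and lower list members below are to be read beside this offset, which the random lists share.

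Adam19 itself had the largest difference of all genes above the floor. Its log2 signal was 11.62 in Adam19+/+ cells and 9.77 in Adam19-/- cells, a difference of -1.85, or 3.60-fold lower. The remaining signal stood at percentile 75.1 of all 19938 genes, against percentile 95.4 in Adam19+/+ cells. The direction of this difference is that of the labels. Which part of the gene was deleted and whether the probes of this cluster lie in it is not given in the sources used here. How far the signal should fall in Adam19-/- cells is therefore not known.

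Few other genes differed by 2-fold. No gene above the floor was 2-fold higher in Adam19-/- cells, and 4 were 2-fold lower, namely Adam19 and the Y-linked genes Eif2s3y, Uty and Kdm5d. At the lower threshold of 1.5-fold, 15 genes were higher and 9 were lower. The largest increase was that of Cntn4, which encodes the neuronal adhesion protein contactin 4, at 7.52 and 8.40, a difference of 0.88 or 1.85-fold. It was followed by Wfdc18 at 0.84, by Bnip3, a hypoxia-inducible mitophagy receptor, at 0.80, and by Myl7, the atrial myosin light chain, at 0.78. The second cluster of Bnip3 gave 0.66. Ociad2 was higher by 0.69, Laptm5, a lysosomal protein of blood cells, by 0.68, Stk26 by 0.67 and C1qb, a complement subunit made by macrophages, by 0.65. The metallothioneins Mt1 and Mt2, which bind zinc and copper, were both higher by 0.65. Epyc, a proteoglycan of cartilage, was higher by 0.64 and the carboxypeptidase gene Cpm by 0.63. Cntn4, Wfdc18, Stk26, C1qb, Epyc and Cpm were above the floor on the Adam19-/- array alone. Adding 32 to the linear signal, which shrinks differences of dim genes, gave 0.78 for Cntn4 and 0.73 for Wfdc18.

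Among the largest decreases after Adam19, Eif2s3y differed by -1.62, Uty by -1.42 and Kdm5d by -1.17. C1qtnf2 differed by -0.91 and Nipal4 by -0.90, each about as large as the largest increase. Mfap5, a protein of elastic microfibrils, was lower by 1.59-fold, from 11.24 to 10.57, and the imprinted non-coding RNA Meg3 by 1.56-fold, from 11.15 to 10.51. Itga7, the laminin-binding integrin alpha 7, differed by -0.60, and Plekha4 by -0.50. Sost, which encodes the Wnt antagonist sclerostin, and the Polycomb-group gene Pcgf1 both differed by -0.48.

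**Figure D1:**
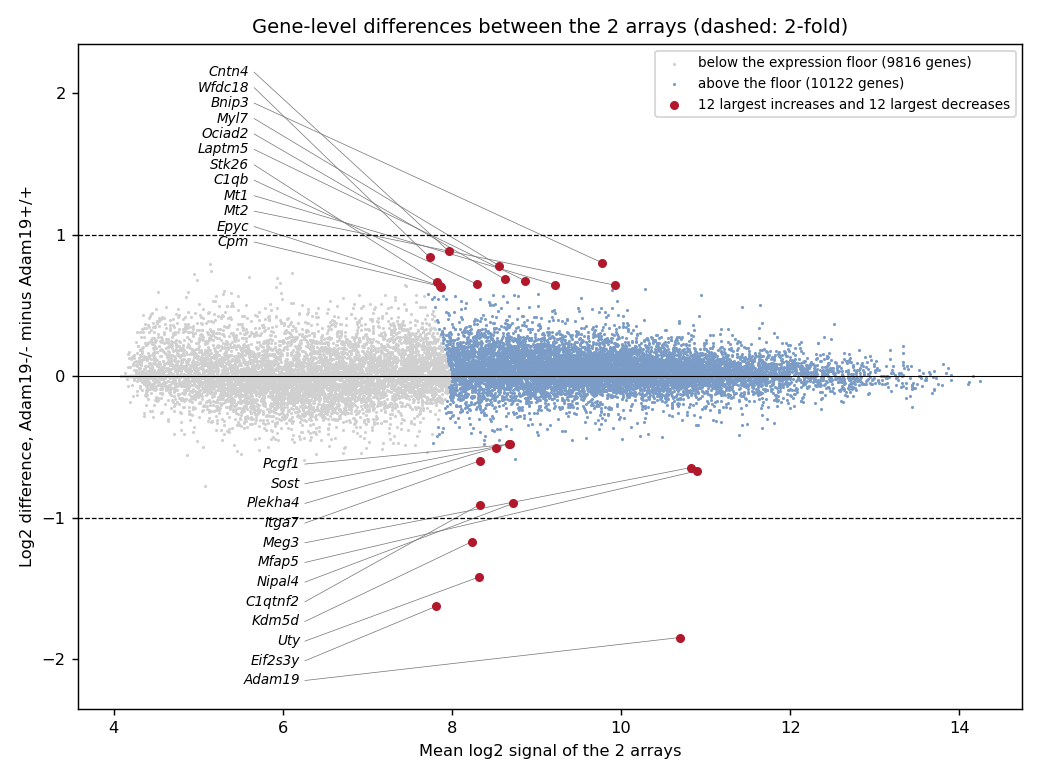
Each point is a gene, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference (Adam19-/- minus Adam19+/+) on the y axis; grey points lie below the expression floor, blue points above it, and red points are the 12 largest increases and 12 largest decreases. Only Adam19, Eif2s3y, Uty and Kdm5d lie beyond the dashed 2-fold lines.

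The samples differed in Y-linked transcripts and at some genes near Adam19. The 3 measured Y-linked genes were between 2.25-fold and 3.08-fold lower on the Adam19-/- array, and with Xist they had a median difference of -1.29. Uty was at 9.03 and 7.61 and Kdm5d at 8.82 and 7.65, and Eif2s3y, at 8.63 in Adam19+/+ cells, was the lowest of them in Adam19-/- cells. All 3 lay under the floor of 8.01 on the Adam19-/- array, as did C1qtnf2 at 7.88. Xist, the RNA of the inactive X chromosome in females, was at 11.25 and 11.14, a difference of -0.11. No measured gene lies between Nipal4 and Adam19, and 13 measured genes lie between C1qtnf2 and Adam19. Of the 193 genes above the floor within 20 Mb of Adam19, 4 or 2.07% differed by at least 1.5-fold, against 0.201% of the 9929 other genes. The 4 include Adam19 itself, and without it 3 are left, 2 of them lower. Of the genes above the floor in the other lists, Hand1 at 0.63, the smooth muscle genes Kcnmb1 at -0.27 and Myocd at -0.07, and the globin gene Hba-x at 0.36 also lie in this window.

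**Figure D2:**
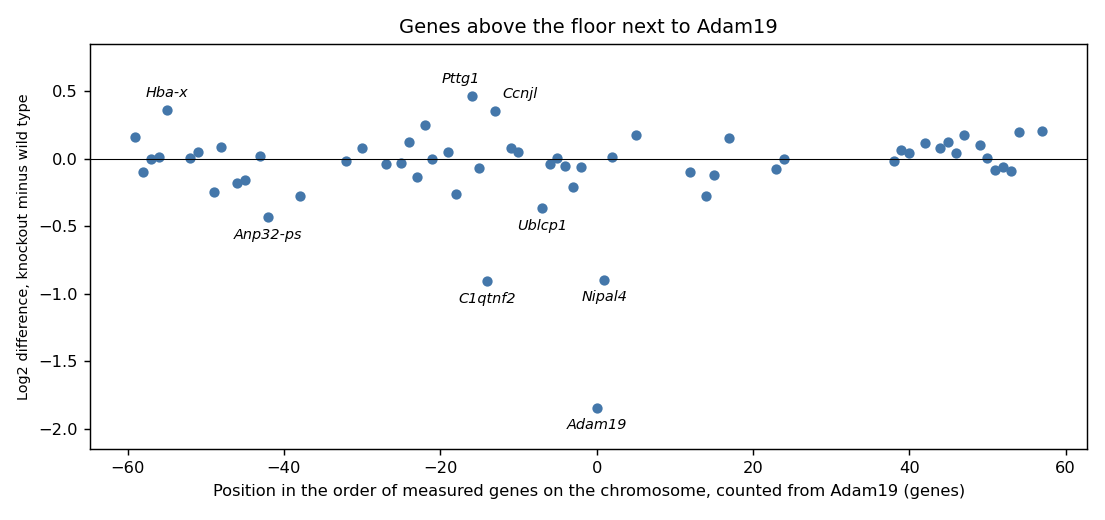
Log2 difference (y axis, knockout minus wild type) of the genes above the floor within 60 measured genes of Adam19, by their position in the order of measured genes (x axis, in genes, Adam19 at 0). Adam19 at -1.85, C1qtnf2 at -0.91 and Nipal4 at -0.90 lie apart from the other points.

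Genes of cartilage were higher in Adam19-/- cells. Of 16 members of the list of cartilage matrix genes and chondrocyte regulators above the floor, 13 were higher and 3 lower, with a median difference of 0.20 or 1.15-fold. Sox9, the transcription factor that starts chondrocyte differentiation, was at 10.65 in Adam19+/+ and 11.23 in Adam19-/- cells, a difference of 0.57 or 1.49-fold, the 20th largest increase of the 10122 genes. Hapln1, which links hyaluronan to proteoglycans, was higher by 0.58 and Col9a1, a chain of cartilage collagen IX, by 0.43. Epyc was higher by 0.64 but lay under the floor in Adam19+/+ cells, at 7.54. The members differed in both directions, since Acan, the main proteoglycan of cartilage, differed by -0.29, Cytl1 by -0.28 and Col9a2 by -0.15. None of the 10000 matched random lists had a median as high, and their central 95% ran from -0.01 to 0.11. With the floor at the 75th percentile of genes only 6 members were left, and their median of 0.08 lay at percentile 76.3 of random lists. On the same array the Y-linked genes were lower and all 16 measured leukocyte markers higher. Genes of bone and hypertrophic cartilage did not share a direction, with a median of 0 over all 15 measured members, 6 of them higher and 6 lower, at percentile 37.3 of random lists. Only 3 were above the floor, with a median of 0.20, namely Dlx5 at 0.36, Pth1r at 0.20 and Mef2c at -0.01.

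Several response genes of bone morphogenetic protein (BMP) signalling were higher in Adam19-/- cells, while the Id genes differed little. The list had 13 members above the floor, 9 higher and 4 lower, with a median of 0.14, at percentile 99.4 of random lists. Hand1, a transcription factor of the developing heart, was higher by 0.63, the BMP-dependent Smad9 by 0.38, and the extracellular BMP modulators Bmper and Grem1 by 0.38 and 0.37. The differences of the Id genes, immediate targets of BMP signalling, were 0.08 for Id1, -0.07 for Id2, 0.04 for Id3 and -0.08 for Id4. Hand1 lies within 20 Mb of Adam19, and without it the median of 0.11 lay at percentile 96.9, inside the central range. With the floor at the 75th percentile, 6 members gave a median of 0.06 at percentile 82.3. On the same array leukocyte markers and 10 of 14 cardiomyocyte markers were higher, and Y-linked genes and 9 of 10 measured transcripts often held in the nucleus lower. BMP ligands, receptors and SMADs had a median of 0.08 over 15 members, 11 higher and 4 lower, within the range of random lists. Among them Bmp2 was higher by 0.34, Bmp6 by 0.32, Bmpr1b by 0.30 and Eng by 0.18, whereas the receptor gene Acvr1 differed by -0.02.

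The lists of TGF-beta, ERBB, other ADAM, Wnt response and fibroblast growth factor response genes lay within the range of random lists. Genes of transforming growth factor beta (TGF-beta) ligands and responses had a median of 0.02 over 14 members, 8 higher and 6 lower, with Tgfbi at 0.37, Tgfb1 at 0.21, Ltbp2 at -0.34 and Tagln at -0.15. The 9 ERBB and neuregulin genes, 4 higher and 5 lower, had a median of -0.03 at percentile 2.55, with Btc at 0.20, Erbb4 at 0.19, Nrg3 at -0.11 and Erbb3 at -0.11. After quantile normalisation the ERBB median was -0.07 at percentile 1.95, below the central range, whereas the mean of the members was 0.01. The 8 other ADAM genes above the floor, 6 higher and 2 lower, had a median of 0.04. Adam23 differed by -0.18, Adam11 by 0.13, Adam17 by 0.10 and Adam9 by -0.07. Wnt response genes had a median of 0.03 over 7 members, 4 higher and 3 lower, led by Lef1 at 0.19, with Axin2 at 0.08, Znrf3 at 0.07 and Dkk2 at -0.06. Genes that respond to fibroblast growth factor had a median of 0.06 over 8 members, 5 higher and 3 lower, with Dusp6 at 0.16, Spry2 at 0.12, Spry4 at -0.12 and Etv5 at 0.10.

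Smooth muscle and Notch genes were lower by small amounts. Of 16 smooth muscle genes above the floor, 15 were lower and 1 was higher, with a median of -0.09, below all 10000 random lists, whose central 95% ran from -0.02 to 0.08. Itga8 differed by -0.41, the potassium channel subunit Kcnmb1 by -0.27, Lmod1 by -0.25 and Cald1 by -0.22. Acta2, which encodes smooth muscle actin, was at 13.74 and 13.62, a difference of -0.12. Of 10 Notch pathway genes, 8 were lower, 1 was higher and 1 was equal, with a median of -0.10 at percentile 0.01. The Notch targets Hey2, Nrarp, Hey1 and Heyl differed by -0.22, -0.21, -0.18 and -0.17. On the same array the transcripts often held in the nucleus had a median of -0.12, and this set was chosen after Meg3 had been seen to be lower. Macrophage markers and 10 of 14 cardiomyocyte markers were higher there.

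Valve and fibrous mesenchyme genes differed in both directions. Of 19 members, 11 were higher, 7 lower and 1 equal, with a median of 0.05, at percentile 87.3 of random lists, whereas their mean of 0.12 lay at percentile 100 and their median after quantile normalisation, 0.08, at percentile 99.4. The largest differences were those of Tcf21 at 0.57, the tendon and valve factor Scx at 0.42, Twist1 at 0.40 and Prrx2 at 0.35, while the related Prrx1 was at 0.04. Among the matrix genes, Eln was at -0.14, Postn at -0.08, Col1a1 at 0.05 and Lum at 0.17.

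**Figure D3:**
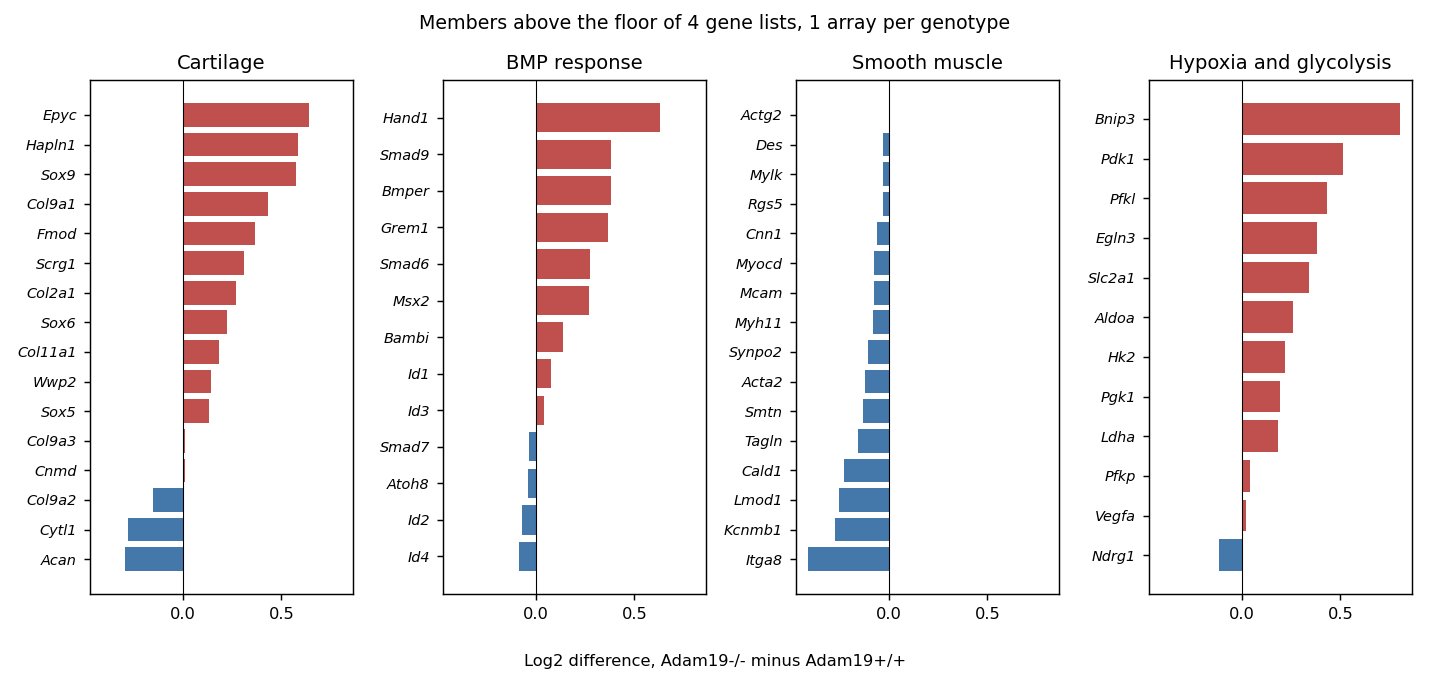
Bars give the log2 difference (x axis, Adam19-/- minus Adam19+/+) of each member above the floor of 4 gene lists, red for higher and blue for lower in Adam19-/-, with 1 array per genotype and no error. Epyc, which is under the floor in Adam19+/+ cells, Hapln1 and Sox9 have the longest cartilage bars, and 15 of 16 smooth muscle genes lie below 0.

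Autonomic neuron genes were higher and glial genes lower by small amounts. Of 18 autonomic neuron genes, 14 were higher and 4 lower, with a median of 0.10 at percentile 99.7. The highest were Th and Dbh, enzymes of catecholamine synthesis, at 0.46 and 0.43, followed by Gata3, a factor of sympathetic neurons, at 0.35 and Stmn3 at 0.21. The 4 lower members were Prph at -0.11, Chrna3 at -0.10, Syt1 at -0.10 and Stmn2 at -0.02. Of 10 Schwann cell and glial genes, 7 were lower and 3 higher, with a median of -0.08 at percentile 0.07. Dhh differed by -0.22, Fabp7 by -0.15, Mbp by -0.15 and Cdh19 by -0.14. With the floor at the 75th percentile the glial median was -0.03 at percentile 10.2. On the same array all 16 leukocyte markers were higher, the Y-linked genes were lower, and the transcripts often held in the nucleus had a median of -0.12. Neural crest and outflow tract regulators had a median of 0.10 over 19 members, 15 higher and 4 lower, at percentile 98.8, with Twist1 at 0.40, Snai1 at 0.30, Foxc1 at 0.29 and Tbx2 at 0.26, but a median of 0.06 at percentile 82.7 with the higher floor. Melanocyte genes had a median of 0.00 over 5 members, 3 higher and 2 lower, with Dct at -0.16, Kit at 0.12, Pmel at 0.02 and Mlana at -0.02.

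Markers of cells that the reporter should not mark were also measured, and those of leukocytes were higher in the Adam19-/- sample. All 16 measured macrophage and leukocyte markers were higher, with a median of 0.31. Only 4 were above the floor, with a median of 0.61, namely Laptm5 at 0.68, C1qb at 0.65, Fcer1g at 0.56 and Cd68 at 0.05, and C1qb and Fcer1g were above it on the Adam19-/- array alone. Cardiomyocyte genes had a median of 0.13 over 14 members, 10 higher, 3 lower and 1 equal, at percentile 98.8. Myl7 was higher by 0.78, Pln by 0.54, Myh6 by 0.39 and Tnni1 by 0.30, whereas Tnnt2 differed by -0.10 and Tnnc1 by -0.22. Myh6 was above the floor on the Adam19-/- array alone. When the clusters of a gene were averaged, the cardiomyocyte median of 0.11 lay at percentile 96.6. Endothelial and endocardial genes had a median of 0.09 over 10 members, 6 higher and 4 lower, within the range of random lists. Nfatc1 was at 0.49, Ramp2 at 0.30, Egfl7 at 0.23 and Kdr at 0.22, while Esam was at -0.14 and Npr3 at -0.12. The 8 measured erythroid markers had a median of 0.047, with 4 higher and 3 lower, at percentile 84.3 of random lists. Only the embryonic globin genes Hba-x and Hbb-y were above the floor, at 0.36 and 0.29 with a median of 0.32. The 4 epicardial markers above the floor had a median of 0.05, and all 11 measured a median of 0. Krt18 differed by -0.23, Tbx18 by 0.21, Aldh1a2 by 0.20 and Krt8 by -0.09.

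Genes of hypoxia and glycolysis were higher in Adam19-/- cells, with 11 of 12 members higher, 1 lower and a median of 0.24 or 1.18-fold. Besides Bnip3, the pyruvate dehydrogenase kinase gene Pdk1 was higher by 0.52, the phosphofructokinase gene Pfkl by 0.43 and the oxygen sensor Egln3 by 0.38. Slc2a1, the main glucose transporter, was higher by 0.34, and Ndrg1 was the member that was lower, at -0.11. None of the 10000 random lists had as high a median, and the list lay above the central range under all 9 alternatives that gave a percentile. Leukocyte markers and 10 of 14 cardiomyocyte markers were higher on the same array, and Y-linked genes and 9 of 10 measured transcripts often held in the nucleus lower. Immediate early and dissociation genes had a median of -0.04 over 16 members, 6 higher and 10 lower, at percentile 0.5, with Ier2 at 0.22, Egr2 at -0.21, Jund at 0.16 and Myc at -0.14. Their mean of -0.02 lay at percentile 3.16. Cell cycle genes had a median of 0.02 over 19 members, 11 higher and 8 lower, with Aurka at 0.18, Aurkb at 0.15, Cenpa at 0.15 and Rrm2 at 0.14, and with Ccna2 at -0.12 and Mki67 at -0.12. Reference genes had a median of 0.03 over 9 members, 6 higher and 3 lower, with Pgk1 at 0.20, Gusb at 0.11, Ywhaz at -0.11 and Ppia at -0.07. Of the 21 lists with a percentile, 6 lay above and 4 below the central 95%. About 1.05 would be expected there if genes varied independently. Members of a pathway or cell type do not, and some lists share members, so these counts do not measure an excess over chance.

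**Figure D4:**
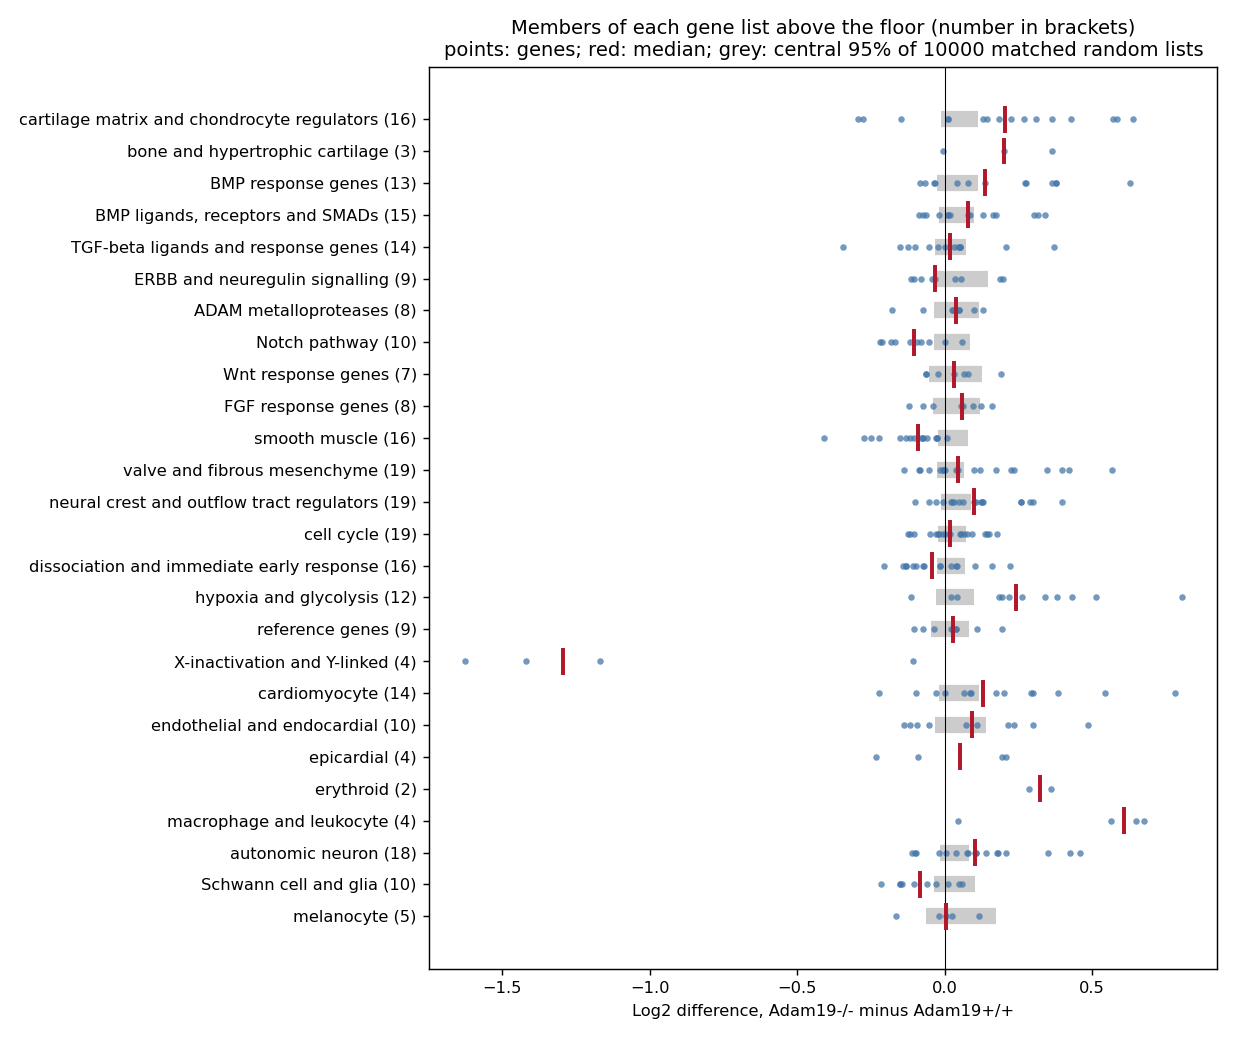
Log2 difference (x axis, Adam19-/- minus Adam19+/+) of the members above the floor of each gene list (y axis, with the number of members in brackets); points are genes, red bars medians and grey bars the central 95% of 10000 random lists matched on mean signal, drawn for lists with at least 5 members. The cartilage, BMP response, neural crest regulator, hypoxia, cardiomyocyte and autonomic neuron medians lie above the grey range, and the Notch, smooth muscle, immediate early and Schwann cell medians below it.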

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

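The tests of a drift of dim probes and of fewer neural crest cells and the look at X-linked genes were chosen after the results were seen, and the test on other leukocyte genes after the markers but before those genes were seen.

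Outside the named genes, 1 transcript cluster with no gene listed in the annotation used here was 2-fold higher in the Adam19-/- sample, by 1.10 on the log2 scale, and 3 were 2-fold lower, down to -1.61. A single one of these 4 reached the expression floor, at 9.71 in Adam19+/+ and 8.19 in Adam19-/- cells. They are singled out because they lie in data that the comparison of named genes does not use.

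The 24 genes at least 1.5-fold apart include 3 Y-linked genes that were lower in the Adam19-/- sample. They also include C1qtnf2 and Nipal4, near Adam19. DNA from the strain in which the gene was targeted may have stayed around the Adam19 locus, although the labels give a C57BL/6 background, and 16.7% of the 24 genes, Adam19 included, lay within 20 Mb of it, between the 25% set in advance as needed for this source and the 10% set to argue against it. For C1qtnf2 and Nipal4 it cannot be told apart from an effect of the deletion on neighbouring genes, and 20 of the 24 genes lay outside the window. A different mix of male and female embryos could lower the Y-linked genes, but their X-linked partners do not decide it, with Kdm6a at 0.40, Eif2s3x and Kdm5c at 0.15, and Ddx3x at 0.03, beside medians of 0.06 for 342 X-linked genes and 0.04 for all genes above the floor. Xist differed by -0.106, where a clear rise had been set as the mark of a larger female share. Xist was bright on both arrays, at 11.25 in Adam19+/+ and 11.14 in Adam19-/- cells. If most Adam19+/+ cells were already female, Xist could not rise that far, so its level cannot decide this. The sex of the samples therefore cannot be told apart from other sources of the Y-linked difference.

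Leukocyte genes were higher in the Adam19-/- sample. A drift of dim probes was argued against, since with no floor the median of all 16 measured markers, 0.31, lay at percentile 100 of random lists of equally dim genes. More leukocyte RNA in the Adam19-/- sort may account for it, since of 20 other leukocyte genes 19 were measured and 17 of them were higher, with a median of 0.16 at percentile 99.99 of such lists. The gate on tdTomato should remove such cells, none of the 19 genes reached the expression floor, and the brightest marker was Laptm5 at 9.21. Whether leukocytes were more frequent in Adam19-/- hearts or passed the gate more often was not tested.

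Cartilage genes were higher and smooth muscle genes lower in the Adam19-/- sample. A drift with signal level between the arrays was argued against, since after centring on a lowess curve the cartilage median was still 0.159 and lay at percentile 100, and the smooth muscle median stayed below the central range. A smaller share of neural crest cells of every kind would by itself lower the smooth muscle, Schwann cell and autonomic neuron medians. The smooth muscle and Schwann cell medians lay below the central range, but the autonomic neuron median lay at percentile 99.72, so these lists did not fall together. Their medians were known when this test was set, so it was no independent check. It does not exclude a smaller share alongside other differences. What stays open is the genotype itself, 2 pools or dissections with other shares of valve mesenchyme, arterial wall and ganglia, and the Y-linked difference. The lower nuclear-retained RNA, whose median of -0.117 was further from 0 than that of smooth muscle, stays open too. More leukocyte or cardiomyocyte RNA stays open for the smooth muscle genes, but dilution alone would not raise the cartilage genes, whose median was 0.20. With 1 array per genotype these were not separable.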

How the results depend on the processing

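Of the alternatives below, only those without genes near Adam19 (and, for the counts, of the Y chromosome) were chosen after seeing the data.

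The Adam19 difference lay between -1.87 and -1.81 under its 4 alternatives. Of 236 alternative values of the lists, 194 stayed close to the reported value and 42 did not. Close meant a shift below the standard deviation of the random-list medians, on the same side of the central range. For lists with no percentile and for named genes it meant a shift below 0.077. Unmatched random lists leave a median unchanged by construction. Leaving out shared members cannot change a list that has none. Averaging clusters changes a list of genes with 1 cluster each only where the floor moves. The 194 therefore include values that are no check. The sign turned in 13 values of 6 lists, those of TGF-beta, ERBB, ADAM, Wnt response, cell cycle and melanocyte genes, and in none of the 10 lists outside the central range. For named genes 451 of 460 values stayed close. Their sign turned in 2 values of 1 gene, and in none of the 55 genes with a difference of at least 0.3. Of the 4 alternatives for Adam19 and each named gene, averaging the clusters cannot change a gene with 1 cluster. Adam19 and most named genes have 1 cluster, so those values were equal by construction and are no check. The Notch, hypoxia and autonomic neuron medians stayed on their side of the central range under all 9 alternatives, and the smooth muscle median under all 10. At 1.5-fold 15 genes were higher and 9 lower. The 4 genes lower by 2-fold became 2 at 3-fold, 1 with the floor at the 75th percentile, and 0 without genes within 20 Mb of Adam19 and of the Y chromosome. With the floor at the 75th percentile, which leaves fewer members, medians were 0.078 for cartilage, 0.061 for BMP response, 0.017 for BMP ligands and receptors, 0.063 for neural crest regulators, -0.072 for immediate early and -0.028 for Schwann cell genes. Too few members for a percentile were left for the 4 ADAM genes at -0.024, the 4 Wnt response genes at -0.041, the 3 cardiomyocyte genes at 0.089 and the single melanocyte gene, Dct, at -0.16. With no floor they were 0.14 for cartilage, 0.27 for BMP response, 0.018 for ERBB, -0.072 for Notch and -0.070 for immediate early genes. After quantile normalisation they were 0.030 for BMP ligands and receptors, -0.070 for ERBB, 0.075 for valve mesenchyme and -0.020 for cell cycle genes. After lowess centring they were 0.16 for cartilage, 0.023 for BMP ligands and receptors, -0.011 for cell cycle, 0.048 for endothelial and 0.080 for autonomic neuron genes. The mean of the members was 0.18 for BMP response, 0.012 for ERBB, -0.13 for smooth muscle, 0.12 for valve mesenchyme, -0.025 for immediate early genes, 0.27 for hypoxia and 0.18 for cardiomyocyte genes. Without Hand1, near Adam19, the BMP response median was 0.11. Averaging the clusters of a gene gave 0.11 for cardiomyocyte genes, and leaving out shared members gave -0.14 for Schwann cell genes. Apart from the thresholds, the genes left out and the smaller lists, the cause was not tested. No paired analysis was possible because each genotype had 1 array, and for the same reason no array could be left out. The number of arrays limits what can be resolved.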

Other observations

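The tests of the imprinted region and of the nuclear RNAs were set before their values were seen, though genes noticed in these data prompted both, and the comparison of the nuclear RNAs with random lists was chosen only after their median was seen.

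Some single genes outside the lists were chosen after their values were seen, and they stand for no group. Has2, which makes the hyaluronan of the endocardial cushions, was higher by 0.53 and Papss2, which supplies sulphate for proteoglycans, by 0.49. Slc18a2, the vesicular monoamine transporter, was higher by 0.40, Maoa, which degrades monoamines, by 0.41 and Gata2 by 0.46. Slc16a3, which exports lactate, was higher by 0.61 and Ak4 by 0.43. Dpt differed by -0.42, Pi16 by -0.36 and Ogn by -0.30.

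Meg3 differed by -0.64 on the log2 scale. Other maternally expressed RNAs of its imprinted region may have been lower too, and Rian, the one measured, differed by -0.207, just past the bound of -0.2. The paternally expressed Dlk1 of the same region was at 13.24 and 13.25. A second hypothesis is a lower share of nuclear-retained RNA in the Adam19-/- sample, since Malat1 differed by -0.36, Firre by -0.40, Nktr by -0.37, Pnisr by -0.33 and Clk1 by -0.32. In 10 other transcripts often held in the nucleus, listed without knowing their values, 9 were lower, with a median of -0.117, and the test was met at the bound of -0.1. Srsf5 differed by -0.29, Ccnl1 by -0.23 and Airn by -0.22. Their median lay below the central 95% of 10000 matched random lists. Such a shift could come from handling or lysis of the cells as well as from biology, and could also hold down Xist, which is nuclear. The effect was small, and 1 array per genotype does not separate these.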
